A study of Arabidopsis thaliana with 8 samples.

How the data were processed

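The samples were 8 RNA-seq libraries of Arabidopsis thaliana seedlings, 2 each of wild type (accession Columbia, Col-0) and of the T-DNA insertion line prp43a, at control temperature and after heat. The labels call the libraries of a group biological replicates. Groups and replicate numbers were taken from the titles of the samples.

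The authors deposited 1 table of 27655 gene rows with TPM (a transcript share: read number corrected for gene length and scaled to a fixed total) for each library, per the file headers. Each column summed to 1000000 over all rows, 88 chloroplast-encoded and 122 mitochondria-encoded rows included. The genome build was TAIR10, per the submitters' processing notes. The aligner, the counter, the annotation version, the strand setting and the handling of reads that fit several genes are not given in the sources used here. Per the labels' protocols, the libraries came from a stranded mRNA kit and were sequenced as paired 75 bp reads on a MiSeq. Such a kit selects polyadenylated RNA, so organelle transcripts were measured only as far as they passed that selection. TPM values are shares: a large rise of some genes lowers all others.

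TPM keeps no depth of its own. Low values lay on whole multiples of a step set by gene length, and with exon lengths from the TAIR10.1 reference annotation (27445 rows had a gene model) 99.2% of 126947 values above 0 and up to 200 reads came out whole within 0.05. The totals recovered this way were 4071041 to 4783641 per library. Whether 1 unit is a read or a read pair is unknown. At 10 TPM, a gene with 1.5 kb of exons rested on 37.0 to 44.7 reads, so genes at a few TPM were measured coarsely.

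Genes with TPM of at least 1 in at least 2 of the 8 libraries were tested (19697 genes). Differences were fitted on log2(TPM + 1) with limma 3.58.1 (moderated test with a mean-variance trend, R 4.3.3), all 8 libraries in 1 fit with a mean per group, 4 residual degrees of freedom, and Benjamini-Hochberg adjustment per comparison, called at adjusted p below 0.05. A log2 fold change is on the log2(TPM + 1) scale and understates the change of low genes. The 5 comparisons were prp43a against wild type at control temperature and after heat, heat against control in each genotype, and the difference of the heat responses (the interaction). With 2 libraries per group no permutation test can reach the threshold, and the p-values rest on the spread shared across genes.

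Gene lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, again with a correlation estimated from the residuals, and with fry, which asks whether a list's genes move one way on balance without comparing them with other genes. The adjustment of fry over the 16 lists of a comparison was added after the data were seen. The lists, the rule for named genes, the comparisons and all alternatives but those named as added were fixed before the data were examined. Of 18 lists, 16 had at least 3 tested members. The seed maturation list had 1 tested member of 12. The 8 loci of the ONSEN retrotransposon list were not analysed here. Named genes were chosen by this rule: per pairwise comparison the 10 highest and the 10 lowest log2 fold changes among called genes with a mean of at least 10 TPM in a compared group and no overlap between the replicates of both groups, which chance gives for 33.3% of genes; for the interaction up to 8 in each direction without the overlap rule; up to 4 called members of each list with the largest change; and the helicase loci AT3G62310 and AT2G47250.

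The fit was tested on simulated TPM tables with 200 changed genes. Reads of each gene were drawn independently, with the same dispersion of 0.02 (spread between replicates beyond sampling) for all genes. The recovery and false-call numbers hold for that spread only. For prp43a at control temperature (19546 genes) it recovered 0 of 50 genes changed 1.5-fold, 13 of 50 changed 2-fold, 48 of 50 changed 4-fold and 48 of 50 changed 8-fold, with 6 false calls among 115. For heat in wild type (18785 genes) it recovered 24 of 50 genes changed 2-fold and 47 of 50 changed 4-fold. For the interaction (19488 genes) it recovered 3 of 50 genes changed 2-fold and 31 of 50 changed 4-fold. In the simulation of prp43a at control temperature (19534 genes), a list of 30 genes raised 1.5-fold gave a camera p of 4.593e-26 with the preset and 0.0003484 with the estimated correlation, and 4 and 1 of 200 random lists fell below 0.05. The simulated genes were independent, so this could not test the preset on correlated lists. In the data the estimated correlation ran from -0.03 for heat shock transcription factors to 0.44 for photosystem genes. No fixed list passed camera with the estimated correlation in any comparison. Small heat shock proteins with heat in wild type were among those that failed (adjusted p = 0.11). Failing this test therefore does not show that a list is unchanged.

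The other settings tried were pseudocounts of 0.1 and 5, no filter and a filter at 5 TPM, median-of-ratios scaling, quantile normalization, TPM without organelle genes, a fit of only the groups compared, no trend, a robust fit, a replicate block, a fold change limit and leaving out each library, where the lone library of a group is assumed to vary like the other groups. Each fit that leaves out a library also loses a residual degree of freedom, so a call lost there need not depend on that library. A limma voom fit on the recovered reads was added after the data were seen. A transcript-level fit was not run, since the table is per gene. Splicing changes could therefore not be assessed in either genotype. Sequence matches used BLAST 2.17.0. If the recovered units were independent reads, no replicate pair agreed within sampling noise: the chi-square of recovered reads per degree of freedom was 1.66 to 3.59. Mates of a pair counted as separate reads would raise this value, and whether they were is unknown.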

Results

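Messenger RNA was measured in seedlings of Arabidopsis that had grown for 7 days at 22 °C under 16 h of light and 8 h of dark, and in seedlings then held at 38 °C for 16 h. The prp43a line carries a T-DNA insertion in PRP43a, which the series title names as a component of splicing disassembly, the step in which a spent spliceosome is taken apart. Wild type and prp43a were each measured in 2 libraries per condition. The depth recovered from the TPM values was 4071041 to 4783641 reads or read pairs per library. Libraries of the same condition correlated across genes at r = 0.976 to 0.985 whatever the genotype, and control against heat libraries at r = 0.743 to 0.767. The first principal component held 90.08% of the variance and separated control from heat. On the second, with 2.39%, wild-type control replicate 1 stood at 34.2, replicate 2 at 6.43 and the prp43a controls at -16.8 and -24.4. Wild-type control replicate 2 correlated with the prp43a controls at r = 0.984 and 0.983 and with its own replicate at r = 0.983, while replicate 1 correlated with the prp43a controls at r = 0.978 and 0.976.

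The genotype labels were checked first at AT3G62310 and AT2G47250, the loci of the homologs of the yeast splicing helicase Prp43, both annotated as RNA helicase family proteins. AT3G62310, on chromosome 3 (23057240 to 23060731, minus strand, TAIR10.1), stood at 28.3 ± 2.18 TPM in wild-type control (SD, n = 2) and 1.56 ± 0.172 TPM in prp43a control (SD, n = 2). After heat it stood at 68.5 ± 5.49 TPM in wild type and 9.26 ± 1.44 TPM in prp43a (SD, n = 2 each). Its log2 fold change in prp43a was -3.52 at control temperature (SE 0.16, limma adjusted p = 2.3e-05) and -2.76 after heat (SE 0.16, limma adjusted p = 0.00023). AT2G47250, on chromosome 2 (19399648 to 19403044, minus strand, TAIR10.1), had 33.4 ± 1.77 TPM in wild-type control and 51.9 ± 3.05 TPM in prp43a control (SD, n = 2 each), a log2 difference of 0.62 that did not pass the test (limma adjusted p = 0.077; 0.048 to 0.52 over the alternatives, the lowest with voom on recovered reads, a fit added after the data were seen). The sources used here do not pair the name PRP43a with a locus. AT3G62310 is the one that was low in the libraries labelled prp43a. In a fit of only the 4 libraries of each condition, the call for AT3G62310 was lost at control temperature (limma adjusted p = 0.20, where the alternatives ran from 2.1e-06 to 0.20) and after heat (limma adjusted p = 0.60, where they ran from 7.3e-08 to 0.60), with the direction kept.

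**Figure D1:**
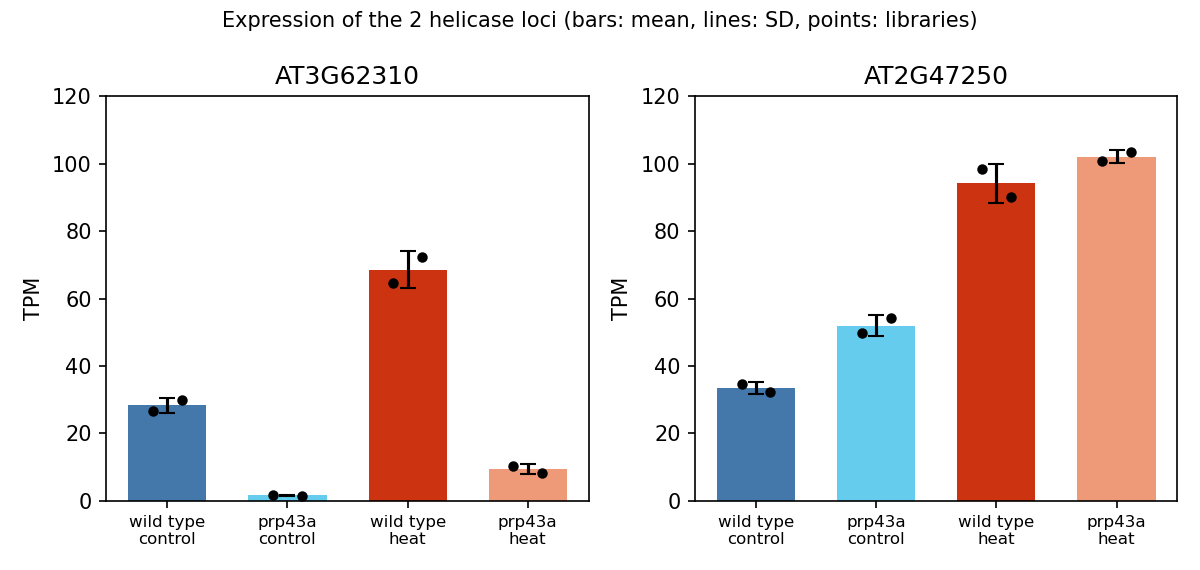
TPM of AT3G62310 (left) and AT2G47250 (right) in the 4 groups. Bars are means, lines SD and points the 2 libraries of a group. AT3G62310 stands at 1.56 TPM in prp43a control against 28.3 TPM in wild-type control.

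At control temperature 14 genes were lower in prp43a, AT3G62310 itself among them. Of the 14, 3 belonged to the fixed list of abscisic acid and dehydration genes. Another 4 belonged to the late embryogenesis abundant proteins, a list added after the data were seen. LEA7, a late embryogenesis abundant protein (a class that protects cells during drying), had 28.8 ± 8.65 TPM in wild type and 1.17 ± 0.598 TPM in prp43a (SD, n = 2 each), a log2 fold change of -3.78 (SE 0.36, limma adjusted p = 0.0038). LTI65, which responds to abscisic acid (the plant hormone of water deficit), fell from 31.4 ± 4.65 to 1.67 ± 0.486 TPM. The dehydrin RAB18_2 (AT5G66400) fell from 90.7 ± 15.9 to 9.81 ± 2.69 TPM. P5CS1, an enzyme of proline synthesis, fell from 83.2 ± 16.5 to 32.6 ± 2.91 TPM. In all, 14 of 19697 genes passed the limma test, each lower in prp43a, and 13 of them by at least 2-fold on the log2(TPM + 1) scale. Some other settings also called higher genes, among them 6 of 21 with no trend, 3 of 18 with no filter and 5 of 48 without wild-type control replicate 2. The late embryogenesis abundant genes AT3G02480, LEA4-5 and AT3G17520 had log2 fold changes of -3.00, -2.87 and -2.61. The lipid transfer protein gene LTP3 and the amino acid transporter gene AT2G41190 had -2.31 and -1.95. EGY3, AT5G01300, AT5G15500 and AT5G45690 also passed, with log2 fold changes of -0.91, -2.33, -2.79 and -2.01; they fell outside the naming rule and were named after their values were seen.

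**Figure D2:**
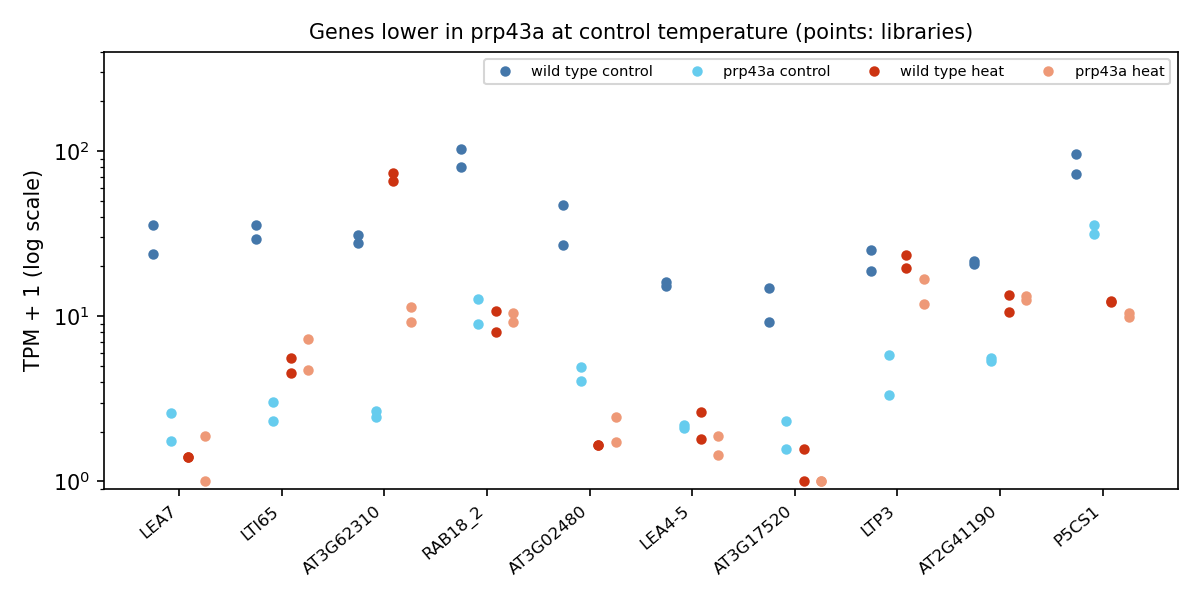
TPM + 1 on a log axis for the 10 called genes that the naming rule took in prp43a at control temperature, each point 1 library. In RAB18_2 the wild-type control mean of 90.7 TPM stands above the prp43a control mean of 9.81 TPM.

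Among the fixed lists, 3 of 24 abscisic acid and dehydration genes fell in prp43a at control temperature and none rose; adjusted over the list alone 13 fell. The list median was -0.51, and 23 of 24 members had a negative log2 fold change (camera adjusted p = 1.7e-19; adjusted p = 0.11 with an estimated correlation). None of the 30 ribosome biogenesis genes passed over all genes, and 14 rose adjusted over the list alone. Their median was 0.29, with nucleolin NUC-L1 at 0.28 and fibrillarin FIB2 at 0.55, both proteins of the nucleolus (camera adjusted p = 7.6e-15; adjusted p = 0.11 with an estimated correlation). None of 21 salicylic acid and defense genes passed over all genes, and 3 fell adjusted over the list alone, with a median of -0.52 (camera adjusted p = 1.6e-06; adjusted p = 0.22 with an estimated correlation). Single defense genes varied between replicates: PAD3 stood at 21.0 and 1.18 TPM in the wild-type control libraries. NUC-L1, FIB2 and PAD3 did not pass over all genes and were named after their values were seen. Without wild-type control replicate 1 the abscisic acid median was -0.33 and the salicylic acid median -0.25, and without prp43a control replicate 1 the latter was -0.27, with the calls kept. The smaller shifts called by camera were a median of -0.19 for small heat shock proteins, -0.15 for heat shock transcription factors, -0.19 for reactive oxygen genes, -0.07 for photosystem genes, 0.10 for HSP70 and HSP90 chaperones, 0.10 for the unfolded protein response, 0.11 for spliceosome components and 0.17 for cell cycle genes; none held with an estimated correlation (adjusted p of 0.22 to 0.595). Adjusted over the list alone, 1 small heat shock protein gene rose and 4 fell, 6 chaperone genes rose, 3 heat shock transcription factors fell, 2 reactive oxygen genes rose and 2 fell, and 1 spliceosome gene and 1 RNA decay gene rose. The 1 spliceosome gene of 52 that fell was AT3G62310 itself. Each of these smaller list calls was lost in some fit that left out a library, and several also under other settings with all libraries kept. Without wild-type control replicate 1 the calls for small heat shock proteins (median -0.03), reactive oxygen (-0.08), photosystem (-0.07), spliceosome (0.09) and cell cycle genes (0.13) were lost. Without wild-type control replicate 2 those for HSP70 and HSP90 chaperones (0.03), the unfolded protein response (0.02), photosystem (-0.08) and spliceosome genes (0.12) were lost. Without prp43a control replicate 1 those for chaperones (0.05), photosystem (-0.07) and reactive oxygen genes (-0.16) were lost. Without prp43a control replicate 2 those for small heat shock proteins (-0.01), heat shock transcription factors (-0.08), the unfolded protein response (0.04), spliceosome (0.06), photosystem (-0.07), reactive oxygen (-0.26) and cell cycle genes (0.17) were lost. With quantile normalization the photosystem median was 0, and the photosystem and reactive oxygen calls were lost. The unfolded protein response and spliceosome calls were lost with the filter at 5 TPM, median-of-ratios scaling, quantile normalization and voom on recovered reads. A pseudocount of 5 also lost the unfolded protein response call. The heat shock transcription factor call was lost with the filter at 5 TPM, and that for small heat shock proteins with voom. The limma test fry gave an adjusted p of 0.042 for the abscisic acid list, 0.034 for ribosome biogenesis and 0.013 for heat shock transcription factors. It did not pass the salicylic acid list (adjusted p = 0.23) or the other lists that camera called (adjusted p of 0.24 to 0.55). The splicing regulator, RNA decay, clock, flavonoid and root lists were not called (camera adjusted p of 0.093 to 0.68); the root list had a median of -0.08 and a mean of 0.08, and the flavonoid list a median of 0.00 and a mean of -0.17.

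Heat libraries enter the comparison at control temperature only through the shared spread, yet leaving 1 out also lowered the number of calls. A lower number therefore need not mean that the calls depend on the library left out. The count at control temperature changed with each library left out, wild-type control replicate 1, which stood apart on the second component, included. It was 6 without wild-type control replicate 1, 48 without wild-type control replicate 2, 4 and 3 without prp43a control replicates 1 and 2, 7 without either wild-type heat library, 8 without either prp43a heat library, and 0 in a fit of only the 4 control libraries, where 1827 genes had an unadjusted p below 0.05. AT3G62310, LTI65 and RAB18_2 passed in each of the 8 fits that left out a library, and LEA7 was lost without either prp43a control library (limma adjusted p = 0.087 and 0.055, in a range of 0.00022 to 0.35 over its alternatives). Of 20 alternatives, the call for AT3G17520 was lost in 14, among them each of the 8 fits that left out a library, those for P5CS1 and LTP3 in 9 each, that for AT3G02480 in 5 and those for LEA4-5 and AT2G41190 in 4 each. P5CS1 was lost in each fit that left out a library but the one without wild-type control replicate 2, and LTP3 in each but those without wild-type control replicate 2 and prp43a control replicate 1. AT3G02480 was lost without either wild-type heat library or either prp43a control library. LEA4-5 and AT2G41190 were lost without wild-type control replicate 1 or either prp43a control library. At an unadjusted p below 0.05 there were 1760 genes, where 985 would be expected by chance; without wild-type control replicate 1 there were 1092, without prp43a control replicate 2 there were 1214, and the other fits that left out a library gave 1494 to 2105.

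After heat, AT3G62310 was the 1 gene of 19697 that passed the limma test between prp43a and wild type. At an unadjusted p below 0.05 there were 899 genes, where 985 would be expected by chance; without wild-type heat replicate 1 there were 1402, without wild-type heat replicate 2 there were 1317, and the other fits that left out a library gave 792 to 899. None of the 16 lists passed camera, with the smallest adjusted p at 0.41 (0.999 with an estimated correlation) and the smallest adjusted fry p at 0.96. Adjusted over the list alone, AT3G62310 was again the 1 member of a list that passed. The dehydrin RAB18_2 stood at 8.40 ± 1.92 TPM in wild type and 8.85 ± 0.931 TPM in prp43a (SD, n = 2 each), and LTI65 at 4.04 ± 0.723 and 4.98 ± 1.77 TPM. The call count was 2 without prp43a heat replicate 1, 3 without prp43a heat replicate 2, and 0 in a fit of only the 4 heat libraries, where 785 genes had an unadjusted p below 0.05.

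Most of the transcriptome of wild type differed between control and heat. The hour of harvest is not given, so a difference in time of day cannot be told apart from heat. That limit holds for each heat comparison below, in both genotypes. Under the naming rule, the largest rises were mostly in small heat shock proteins, chaperones that hold unfolding proteins: HSP21 of the chloroplast went from 1.08 ± 0.0189 to 5002 ± 644 TPM (SD, n = 2 each), a log2 fold change of 11.22 (SE 0.10, limma adjusted p = 3.6e-12). ATHSP22.0, AT1G53540, HSP17.4, HSP18.2, HSP23.6-MITO, HSP17.6II and AT2G29500 had log2 fold changes of 8.69 to 10.73. APX2, a peroxide-scavenging ascorbate peroxidase, rose from 0.99 to 571 TPM. The mitochondria-encoded atp1 rose from 0.92 to 581 TPM. The largest falls included light-harvesting proteins of photosystem II: LHCB2.3 went from 1843 ± 68.7 to 1.12 ± 1.24 TPM and CAB2 from 9436 ± 215 to 212 ± 29.2 TPM. Many members of this family and of the small heat shock proteins are near-identical in sequence, so the split of reads between them is uncertain. FRO6 (an iron reductase of leaves), the extensin-like gene ELP, IGMT4, CYP79F1, AT5G48490 and AT2G27402 had log2 fold changes of -5.43 to -6.48.

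In all, 13784 of 19697 genes passed in wild type, 8342 higher and 5442 lower, and 13813 passed in prp43a, 8492 higher and 5321 lower. The median gene rose by 0.25 in wild type and 0.28 in prp43a on the log2 scale. With median-of-ratios scaling the median was 0.00 in wild type, and higher genes were 49.6% of calls against 60.5% as deposited; in prp43a they were 49.2% against 61.5%. With quantile normalization they were 52.5% and 52.0%. The number of genes called and also changed at least 2-fold was 8360 in wild type and 8346 in prp43a.

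Of 16 small heat shock protein genes 15 rose and 1 (AT4G21870) fell in wild type, with a median of 8.24, and their summed share went from 0.0151% to 4.60% of TPM. Of 26 HSP70, HSP90 and HSP101 chaperone and co-chaperone genes 25 rose, with a median of 2.86: the immunophilin AT5G48570 went from 17.9 to 4240 TPM and HSP90.1 from 30.4 to 1548 TPM. Of 20 heat shock factors and MBF1C 14 rose and 2 (HSFA6A and HSFB4) fell, HSFA3 going from 2.25 to 153 TPM and HSFA2 from 3.41 to 87.7 TPM. Of 18 genes of the unfolded protein response 14 rose and none fell, the chaperone BIP2 from 102 to 799 TPM. AT4G21870, HSFA6A and HSFB4, and SAD1 of the spliceosome list, were named after their values were seen. Camera called these 4 lists higher (adjusted p of 9.0e-12 to 0.013; adjusted p of 0.11 to 0.20 with an estimated correlation).

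RNA-processing genes rose as well. Of 52 spliceosome genes 50 rose and 1 (SAD1) fell in wild type, with a median of 1.19: EMB2770, a pre-mRNA splicing factor, went from 19.6 ± 0.099 to 172 ± 4.39 TPM and the core protein SmD3 from 31.2 ± 0.859 to 152 ± 31.3 TPM (SD, n = 2 each). Of 24 SR proteins and other splicing regulators 21 rose and none fell, GRP7 from 82.5 to 3307 TPM and SR30 from 42.8 to 303 TPM. Of 30 ribosome biogenesis genes 29 rose (30 adjusted over the list alone, where the other lists kept their counts in wild type), with a median of 1.71, the helicase PRH75 from 65.3 to 441 TPM. Of 15 RNA decay genes 13 rose, RRP4 of the exosome from 10.7 to 53.5 TPM. Both helicase loci rose in wild type, AT3G62310 by 1.25 and AT2G47250 by 1.47 (limma adjusted p = 6.7e-05 and 5.0e-07). The 4 list calls had camera adjusted p of 6.8e-11 to 0.0052 and adjusted p of 0.081 to 0.28 with an estimated correlation. Under median-of-ratios scaling the medians stayed above 0, at 0.91 for the spliceosome list and 0.41 for RNA decay.

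**Figure D3:**
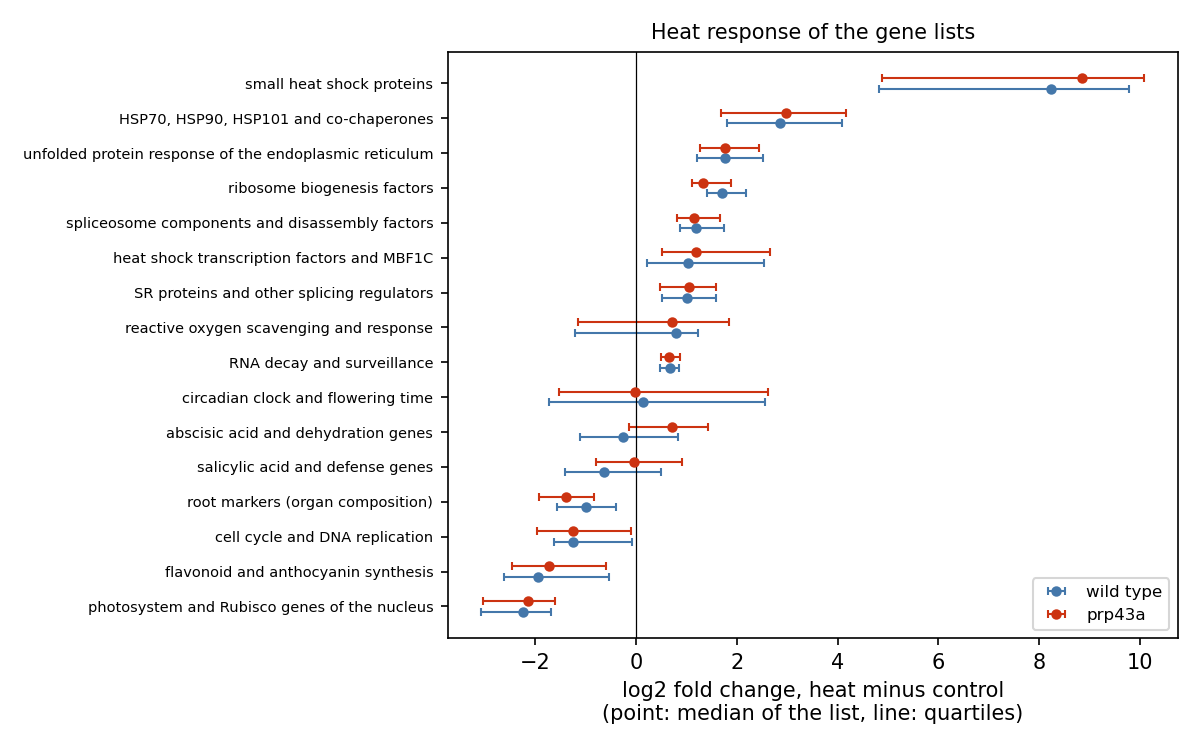
Log2 fold change with heat of the 16 tested gene lists in wild type (blue) and prp43a (red), points for list medians and lines for quartiles. Small heat shock proteins had medians of 8.24 in wild type and 8.85 in prp43a, and photosystem genes -2.24 and -2.14.

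Photosystem and Rubisco genes fell: 30 of 31 in wild type and 31 of 31 in prp43a, and their summed share went from 18.9% to 5.14% of TPM in wild type. Of 9 flavonoid genes 7 fell, and DFR was listed at 0 in each heat library against 21.5 ± 4.99 TPM in wild-type control. Of 19 cell cycle genes 12 fell and 4 rose, the cyclin CYC1BAT from 15.5 to 0.30 TPM. Of 9 root markers 5 fell and none rose, PYK10 from 1092 to 129 TPM; the root median was -0.99, and -0.62 without wild-type control replicate 2. Camera called these 4 lists lower in wild type (adjusted p of 5.4e-19 to 0.011; adjusted p of 0.11 to 0.20 with an estimated correlation). The lists for abscisic acid, salicylic acid, reactive oxygen and the clock were not called with heat. Their members moved both ways: in wild type 7 of 24 abscisic acid genes rose, as KIN2 from 22.0 to 219 TPM, and 9 fell, as RAB18_2. Of 21 salicylic acid genes 4 rose, WRKY18 by 2.28, and 11 fell, PR1 with a log2 fold change of -3.84. Of 13 reactive oxygen genes 9 rose and 4 fell. Of 21 clock and flowering genes 8 rose, as ELF4 from 2.94 to 92.5 TPM, and 7 fell, as LHY from 34.4 to 1.82 TPM. The abscisic acid list had a median of -0.25 and a mean of 0.03 in wild type. For the clock list camera pointed down in both genotypes while the means were 0.51 and 0.53. The hour of harvest is not given in the sources used here.

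The lists that camera called with heat also passed fry, with an adjusted p of 5.6e-06 to 0.00079 in wild type and 4.0e-06 to 0.00049 in prp43a. Fry, which does not compare a list with other genes, also passed lists that camera did not call, each upward: reactive oxygen and clock genes in wild type (adjusted p = 0.00065 and 0.0054) and in prp43a (adjusted p = 0.00040 and 0.0060), and abscisic acid genes in prp43a (adjusted p = 0.0064).

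In gene totals, the heat response of prp43a was close to that of wild type. Intron retention and other splicing changes cannot be seen in a table of gene totals and were not measured. Across the 19697 genes, which are not independent replicates, the log2 fold changes correlated at r = 0.961 with a slope of 0.95, and both comparisons called 7616 genes higher, where independent lists would share 3597, and 4714 lower, where independent lists would share 1470. Opposite calls were made for 9 genes. In prp43a, HSP21 rose by 10.52 and ATHSP22.0 by 11.49, LHCB2.3 had a log2 fold change of -9.63 and AT3G62310 rose by 2.00. In prp43a 15 of 16 small heat shock protein genes rose, 25 of 26 chaperones, 14 of 20 heat shock factors, 15 of 18 unfolded protein response genes, 50 of 52 spliceosome genes (51 adjusted over the list alone), 19 of 24 splicing regulators, 29 of 30 ribosome biogenesis genes and 12 of 15 RNA decay genes. In prp43a 7 of 9 flavonoid genes fell and 1 rose, 12 of 19 cell cycle genes fell (13 adjusted over the list alone) and 4 rose, and 6 of 9 root markers fell. Camera called the same 12 lists as in wild type, the 8 risen ones higher and the photosystem, flavonoid, cell cycle and root lists lower (adjusted p of 1.4e-19 to 0.0062; adjusted p of 0.088 to 0.30 with an estimated correlation). Of the lists not called, 12 of 24 abscisic acid genes rose and 4 fell, 6 of 21 salicylic acid genes rose and 7 fell (median -0.03, mean 0.08), 8 of 13 reactive oxygen genes rose and 4 fell, and 8 of 21 clock genes rose and 7 fell. AT5G16030, EXPA8 (an expansin, a cell wall loosening protein) and AT4G10060 were among the 10 lowest in prp43a, at -5.66, -5.64 and -5.35. The mutant effects at control temperature and after heat correlated at r = 0.03 across genes. After heat 899 genes had an unadjusted limma p below 0.05, where 985 would be expected by chance. An r near 0 is thus what noise alone would give, and it does not show that the mutant effect differs between conditions. The 14 and 1 called genes shared AT3G62310.

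**Figure D4:**
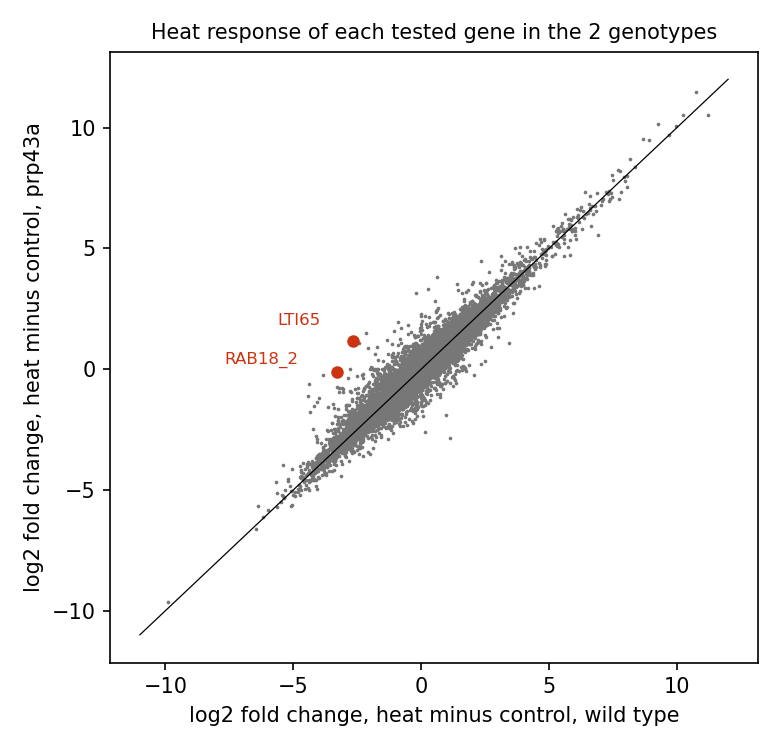
Log2 fold change with heat of each of the 19697 tested genes in wild type (horizontal) and prp43a (vertical), with the line of equal change. The marked genes, LTI65 and RAB18_2, passed the test of the difference.

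The heat response differed between the genotypes for 2 genes. Both were lower in prp43a at control temperature, and neither passed between the genotypes after heat. The difference in response thus repeats the control difference and is not a second, separate result. RAB18_2 fell by 3.29 with heat in wild type and had a log2 fold change of -0.12 in prp43a, a difference of 3.18 (SE 0.31, limma adjusted p = 0.013). LTI65 fell by 2.68 in wild type and rose by 1.15 in prp43a, a difference of 3.83 (SE 0.37, limma adjusted p = 0.013). Of the lists, camera called the abscisic acid and dehydration genes (median difference 0.65, adjusted p = 5.8e-15), the salicylic acid genes (0.44, adjusted p = 0.0058), the ribosome biogenesis genes (-0.31, adjusted p = 1.3e-09) and the HSP70, HSP90 and HSP101 list (-0.07, adjusted p = 0.035); none held with an estimated correlation (adjusted p of 0.24 to 0.58). In the order of these lists, the medians between genotypes were -0.51, -0.52, 0.29 and 0.10 at control temperature. After heat they were 0.07, 0.02, 0.02 and -0.01, so the list differences too came from the control libraries. Of 24 abscisic acid genes 2 had a higher response in prp43a, 5 adjusted over the list alone, and of 21 salicylic acid genes 0, 3 adjusted over the list alone. The salicylic acid call was lost without wild-type control replicate 1 (median 0.30), wild-type heat replicate 2 (0.47), prp43a control replicate 1 (0.18) or prp43a heat replicate 2 (0.31). The HSP70 call was lost without wild-type control replicate 2 (median -0.01), prp43a control replicate 1 (-0.07) or prp43a heat replicate 2 (-0.01), and its median was 0.02 without wild-type heat replicate 1. None of the lists passed fry, with an adjusted p of 0.12 for the abscisic acid list, 0.15 for ribosome biogenesis, 0.62 for the salicylic acid list and 0.69 for the HSP70 list, and the smallest, 0.059, for heat shock transcription factors. AT3G62310 and AT2G47250 had differences of 0.75 and -0.51 that did not pass (limma adjusted p = 0.70 and 0.64). That of AT3G62310 ran from -0.03 with a pseudocount of 5 to 1.24 with voom on recovered reads. The calls for RAB18_2 and LTI65 were lost in each of the 8 fits that left out a library, with a count of 0 in each and 866 to 1612 genes at an unadjusted p below 0.05.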

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

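The tests of explanations in this part were chosen after the result was seen; the test of differing heat responses was not. The results in this paragraph were picked out because the heat response differed between the genotypes in the interaction test. RAB18_2 (AT5G66400) had a difference of 3.18 and LTI65 (AT5G52300) of 3.83 on the log2 scale (limma adjusted p = 0.013 each; 0.0029 to 0.34 and 0.0029 to 0.21 over their alternatives). Both were lost in each of the 8 fits that left out a library, with a pseudocount of 0.1, with no filter and with no trend. The abscisic acid and dehydration list had a median difference of 0.65, the salicylic acid and defense list 0.44, the ribosome biogenesis list -0.31 and the HSP70, HSP90 and HSP101 list -0.072. With an estimated correlation their adjusted p was 0.24, 0.51, 0.24 and 0.58. Neither gene and none of these lists passed between the genotypes after heat, so these differences repeat those at control temperature.

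The abscisic acid and dehydration genes were lower in prp43a at control temperature, with a list median of -0.51, 3 of 24 members called, and a list call that was lost with an estimated correlation (camera adjusted p = 1.7e-19; adjusted p = 0.11 with an estimated correlation). After heat the median between genotypes was 0.071. Wild-type control replicate 1 stood apart from the other control libraries on the second principal component, at 34.2 against 6.43 for replicate 2, and carried part of this difference. One wild-type control library out of place as the whole source is argued against: without wild-type control replicate 1 the list median was -0.33, without replicate 2 it was -0.71, so both libraries gave a negative median. Seed or embryo material left in the wild-type control seedlings is argued against too: 12 seed maturation genes summed to at most 2.25 TPM in a wild-type control library, against an excess of 80.9 TPM for RAB18_2 alone. A different water status or handling of the control seedlings of the genotypes cannot be told apart from an effect of the insertion, because genotype and handling fall on the same libraries, and the median of 0.071 after heat goes with either. An effect of the insertion stays open as an untested hypothesis.

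The remaining AT3G62310 signal in prp43a rose with heat, by 2.00 on the log2 scale and 5.94-fold in mean TPM. It was taken up because it was still present in the insertion line. Its rise was not shown to differ from that in wild type, 2.42-fold in mean TPM: the difference of 0.75 did not pass (limma adjusted p = 0.70, with 0.50 to 0.998 over its alternatives) and was -0.03 with a pseudocount of 5. Reads shared with the paralog AT2G47250 as the whole source are argued against: the remaining signal was 2.66% to 3.38% of the paralog in control and 7.96% to 10.2% in heat libraries, so the lowest heat share was 2.36 times the highest control share. The exons of both loci share no word of 75 bases in the TAIR10.1 reference, and their longest shared run is 59 bases. Some reads placed at the wrong locus with mismatches cannot be excluded, since the aligner settings are not given. Wild-type RNA or seedlings mixed into the prp43a libraries cannot be told apart from transcription at the insertion allele: the signal was 5.52% of wild type in control and 13.5% after heat, and too few other genes differ between the genotypes to measure such a share.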

How the results depend on the processing

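The voom fit on recovered reads was added after the data were seen. Of 3445 values of named genes under alternatives, 3362 kept their side of the threshold, 82 lost it and 1 gained it. These totals pool large heat effects with genotype effects. Several genotype calls, such as AT3G17520, P5CS1 and LTP3, and both interaction calls were lost far more often than most heat calls. A value that was not called changed sign: the AT3G62310 difference in heat response, 0.75, was -0.03 with a pseudocount of 5. Of 815 list values, 732 kept their call, 81 lost it with the sign kept, and 2 lost both: the photosystem median at control temperature went to 0 with quantile normalization, and the HSP70 and HSP90 median of the interaction turned to 0.018 without wild-type heat replicate 1, in a leave-one-out range of -0.147 to 0.018. Unless named here, the cause was not tested. At control temperature, calls were 14, and 21 with no trend, 21 with a pseudocount of 0.1 and 3 to 48 in leave-one-out fits. In a fit of only the groups compared, which has fewer samples, calls were 0 at control temperature and 0 after heat. After heat, calls were 1, and 2 with no filter, 6 with no trend and 1 to 3 in leave-one-out fits. The interaction called 2 genes, and 0 with a pseudocount of 0.1, 7 with a pseudocount of 5, 0 with no filter, 4 with a filter at 5 TPM, 0 with no trend, 5 with the robust fit and 0 in every leave-one-out fit. Where the limma count was 0, unadjusted p below 0.05 held 1228 genes (pseudocount 0.1), 1491 (no filter), 1229 (no trend) and 866 to 1612 (leave-one-out). Voom on the recovered reads called 13 at control temperature, 1 after heat, 3 in the interaction, 13817 by heat in wild type and 13753 in prp43a. Asking also for a 2-fold change left 8360 and 8346 heat calls, by construction. The correlation of the heat responses was 0.961, with Spearman's rho 0.950, 0.979 over genes of at least 10 TPM and 0.947 to 0.959 in leave-one-out fits; that of the mutant effects was 0.03, and 0.0025 to 0.041. Replicate numbers did not pair the samples: deviations of equal numbers correlated at -0.03 to 0.03. With the replicate block, calls were 10, 1, 13748 and 13746 for the pairwise comparisons and 4 for the interaction. Depth of 4071041 to 4783641 per library limits genes at a few TPM. A transcript-level fit was not run.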

Other observations

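The lists and tests in this part were chosen after the data were seen, except the test of nuclear copies, whose bound was set before its result. Adjusted p of lists in this part covers only the 4 added lists of a comparison. The fixed lists were adjusted over 16, so the adjusted values of added and fixed lists cannot be set side by side. Genes of aliphatic glucosinolate synthesis, which make sulfur-rich defense compounds of the cabbage family, fell together with heat. All 17 of the list fell in both genotypes, with a median of -3.39 in wild type and -3.56 in prp43a (camera adjusted p = 3.0e-12 and 1.2e-12; adjusted p = 0.029 and 0.027 with an estimated correlation). The list was drawn up after members such as CYP79F1 had been seen among the lowest genes, so these values are not independent evidence. MAM1, the chain-elongating synthase, went from 234 ± 28.4 to 4.64 ± 0.261 TPM in wild type (SD, n = 2 each), CYP83A1 from 214 to 5.46 TPM, and the regulator MYB28 from 42.9 ± 0.136 to 5.64 ± 1.71 TPM. Late embryogenesis abundant proteins, taken by product name, had 4 of 54 genes lower in prp43a at control temperature and none higher, with a median of -0.08 (camera adjusted p = 0.0014; adjusted p = 0.046 with an estimated correlation). That list too holds genes that prompted it. Its camera p with an estimated correlation was 0.0116 before adjustment. The fixed abscisic acid list had 0.0117 in the same test, which gave an adjusted p of 0.11 over 16 lists.

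Mitochondria-encoded transcripts rose with heat in both genotypes. Their summed TPM went from 35.1 ± 1.79 to 7595 ± 7.98 in wild type and from 35.1 ± 1.97 to 7591 ± 208 in prp43a (SD, n = 2 each), and 97 of 103 tested genes rose in wild type, with a median of 4.46 (camera adjusted p = 4.4e-20; adjusted p = 0.0017 with an estimated correlation). General carry-over of organelle RNA is argued against, since chloroplast-encoded TPM rose at most 1.44-fold while the mitochondrial sum rose 217-fold in wild type. Nuclear copies of mitochondrial DNA in the reference stay open: of 11 genes matched by name, 2 had no nuclear copy, cox1 and nad4L, and their median rise was 7.10 on the log2 scale, but at least 5 such genes had been asked for, and copies missing from the assembly cannot be seen. A change in the amount or the polyadenylation of mitochondrial RNA stays open and was not tested.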
